A study of Bos taurus with 14 samples.

How the data were processed

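Cumulus cells are the somatic cells that surround the oocyte, and here they came from cattle (Bos taurus). The 14 libraries were each made from cells pooled from 10 cumulus-oocyte complexes. Groups were taken from the sample labels by the fate of the oocyte: 4 libraries whose oocytes did not cleave (Cl-, replicates 1 to 4), 5 whose oocytes cleaved but formed no blastocyst (Bl-, replicates 5 to 9) and 5 whose oocytes became blastocysts (Bl+, replicates 10 to 14). Replicate numbers are the library numbers in the sample titles, and they give no pairing between groups. The sources used here do not say whether the pools came from separate animals or collection days, or which pools shared one, so a shared block is unknown and p-values measure only the spread between these libraries, part of which may be technical.

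Per the labels' protocols, total RNA was isolated with magnetic beads and treated with DNase, and 50 to 100 ng went into a stranded poly-A library kit with 15 cycles of PCR and paired reads of 76 bases. Poly-A selection leaves most RNA without a poly-A tail unmeasured. The adaptors carried molecular identifiers, per the labels' protocols. Whether copies were collapsed before quantification is not given in the sources used here, so PCR copies may be counted as separate fragments.

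The deposited values are TPM (transcripts per 1000000), which the authors estimated per Ensembl transcript with kallisto after read checks and trimming with FastQC and fastp, per the submitters' processing notes. Tool versions, the transcript release and the genome build are not given in the sources used here. Kallisto shares reads among transcripts that hold the same sequence, so the level of 1 isoform depends on the isoforms and near-identical copies listed beside it. The table listed 38030 transcripts with their length and effective length, and the columns of all libraries each summed to 1000000 TPM. TPM are relative: a rise of abundant transcripts lowers all others.

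TPM do not carry the read total, but the effective lengths allowed it to be read approximately. Values multiplied by effective length fell at multiples of a common step, taken as 1 fragment, and 48.4% to 52.2% of the low values per library lay within 0.03 of a whole multiple. The total divided by this step gave 28.6 to 39.8 M fragments (M, 1000000) per library. The remaining low values were not whole. Because the deposited values were only TPM, the count test planned for count tables was not run, and the test fixed for TPM was used.

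Transcripts with at least 1 TPM in at least 4 libraries were kept, 20488 in all. Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend of the variance and 1 fit over the 3 groups, so that all groups shared the estimate of spread. Differences are on this log2 scale, which understates the change of transcripts with few TPM. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the transcripts of each comparison, and the threshold was 0.05. The comparisons were Bl+ with Bl-, Bl+ with Cl-, Bl- with Cl-, Bl+ and Cl- each with the other 2 groups, and a joint test of the 3 groups. Library measures were compared by exact permutation tests, two-sided, over 252 arrangements of the labels for Bl+ with Bl- and 126 for the other pairs. Distances between libraries were root mean square differences of log2(TPM + 1), and their grouping was tested with 100000 permutations.

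The groups, the comparisons, the tests for each unit and the other settings to try were fixed before the data were examined. That plan foresaw sums per gene, 30 gene lists with 719 genes and a rule for naming genes, and these could not be applied. The reference table given with the series held 37063 bovine genes, 0 of them with an Ensembl identifier, and 0 transcript identifiers matched it. Transcripts therefore stand without gene names, under their identifiers except for a transcript given by its length of 812 bases. A replacement rule was written once the identifiers had been seen and before any test: from the pairwise comparison with the most calls, up to 2 transcripts in each direction by size of change among those past the threshold, or the 2 with the smallest p where none passed, as values only. ENSBTAT00000018261.6 and a transcript of 812 bases were added after their values were seen.

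The procedure was tested on simulated data for Bl+ against Bl-, with 200 of 20488 transcripts changed in each of 20 draws. The simulated spread came from all 14 libraries, shuffled across the 3 groups, so Cl- libraries also entered it. Of the transcripts changed 2-fold, 57.4% were recovered (46% to 66% per draw), and 87.8% of those above 10 TPM. Of those changed 4-fold, 83.6% were recovered, and 98.4% of those above 10 TPM. On average 2.08% of the calls were false, and 10.7% in the worst draw. Recovery depends on how many transcripts change, because the Benjamini-Hochberg cutoff is stricter with fewer.

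Alternatives were rescaling by trimmed means (30% trimmed by ratio and 5% by level), quantile normalization, 2 other filters on low values, pseudocounts of 0.1 and 5, limma without the trend or with array weights, an adjusted threshold of 0.10, fits of only the groups compared, and each library left out in turn. Leaving out Bl+ replicates 12 and 14 together, removing each library's trend on transcript length, removing the 100 most abundant transcripts and rescaling the rest, and robust variance estimation were chosen after seeing the data. The 100 transcripts removed were those with the highest mean TPM over all libraries, the same set in each. Surrogate variables were not estimated.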

Results

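RNA was sequenced from cumulus cells, the somatic cells around the oocyte, to ask whether their transcript levels differ with what the oocyte later does. The oocytes of 4 pools did not cleave (Cl-), those of 5 pools cleaved without forming a blastocyst (Bl-), and those of 5 pools became blastocysts (Bl+). Of 38030 listed transcripts, 20488 passed the filter on low values and 4877 were at 0 TPM in all 14 libraries. Cl- libraries held 33.3 ± 5.55 M fragments (M, 1000000; SD, n = 4), Bl- libraries 32.7 ± 3.98 M (n = 5) and Bl+ libraries 33.7 ± 3.86 M (n = 5). Exact permutation tests of depth between pairs of groups gave p = 0.770 to 0.921. Transcripts at 1 TPM or more numbered 19486 ± 259 in Cl-, 19444 ± 380 in Bl- and 19019 ± 618 in Bl+.

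The 3 groups of cumulus cells were close to each other in overall expression. Libraries correlated with Spearman coefficients between 0.946 and 0.978 across transcripts, which are not independent replicates, and the mean was 0.968 both within and between groups. The mean distance between libraries was 0.498 within groups and 0.500 between groups (permutation test, one-sided p = 0.374). The first principal component held 23.8% of the variance and the second 15.4%, and the groups overlapped on both. Bl+ libraries were the most dispersed, with a mean distance to each other of 0.550, against 0.476 in Bl- and 0.448 in Cl-. Bl+ replicate 14 had the highest score on the first component (49.4) and Bl+ replicate 12 the lowest on the second (-53.0). The 100 most abundant transcripts of each library, ranked within it, took 28.8% ± 0.88 of the TPM in Bl+ (n = 5), 27.3% ± 1.11 in Bl- (n = 5) and 27.5% ± 0.90 in Cl- (n = 4). That share differed between Bl+ and Bl- with p = 0.0476 by an exact permutation test and an adjusted p of 0.592 over 18 tests of library measures, none of which passed the threshold.

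**Figure D1:**
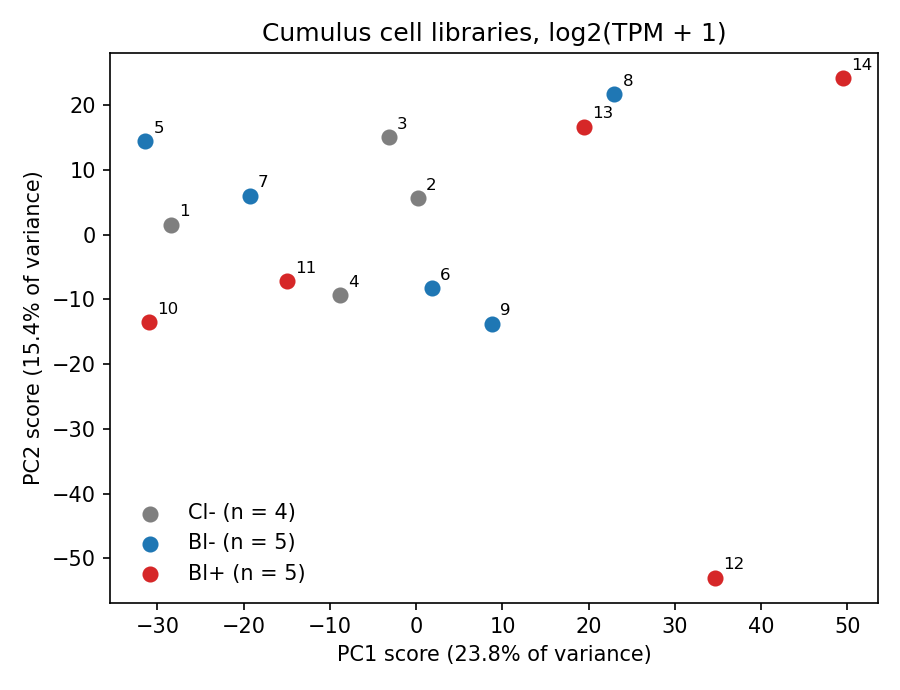
Scores of the 14 libraries on the first (x axis) and second (y axis) principal components of log2(TPM + 1), with 1 point per library labelled by its replicate number and coloured by group. The groups overlap, and Bl+ replicates 12 and 14 lie farthest from the rest.

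Bl+ was compared with Bl- to ask whether cumulus cells of oocytes that reached the blastocyst stage differed from those of oocytes that stopped after cleavage. No transcript passed the adjusted threshold in limma, and the smallest adjusted p was 0.151. For 18396 of 20488 transcripts (89.8%) the unadjusted 95% interval of the difference lay inside a 2-fold change of TPM + 1 in either direction. That share followed the pseudocount, at 76.2% with 0.1 and 98.5% with 5, so it does not bound changes at few TPM. The leading transcript among those lower in Bl+, ENSBTAT00000018261.6 (4497 bases, chosen after its values were seen), was at 71.6 ± 12.6 TPM in Bl+ (n = 5), 128 ± 14.7 in Bl- (n = 5) and 120 ± 17.6 in Cl- (n = 4). Its difference between Bl+ and Bl- was -0.84 (SE 0.125, adjusted p = 0.151), and all 5 Bl+ libraries lay below all Bl- libraries. A transcript of 812 bases, also chosen after its values were seen, had the smallest p among rises in Bl+ against the other 2 groups. Its values in every group therefore entered that choice, so its comparisons are not separate support. It was at 493 ± 62.5 TPM in Bl+ and 332 ± 30.9 in Bl- (n = 5 each), with a difference of 0.56 (SE 0.095, adjusted p = 0.151).

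At an unadjusted p under 0.05 there were 1741 transcripts between Bl+ and Bl-, where 1024 would be expected with no difference. Of these, 1374 were lower in Bl+ and 367 higher, so 78.9% were lower. That balance moved with the scaling, and turned under 2 of 3: after rescaling by trimmed means 656 were lower and 859 higher (43.3% lower), after quantile normalization 683 and 910 (42.9%), and with the 100 most abundant transcripts removed and the rest rescaled 1068 and 516 (67.4%). Without Bl+ replicates 12 and 14, 975 were lower and 567 higher (63.2%). Before rescaling, all 5 Bl+ libraries lay below all 5 Bl- libraries for 278 transcripts and above them for 69, against 81.3 each by chance (0.397%). A shift of library level enters these counts. The counts by p and by separation vary widely between groupings: of 100 splits of these 10 libraries, the real one included, 25 gave as many transcripts at an unadjusted p under 0.05 and 11 separated as many in a direction. Limma without the variance trend and with array weights also made no call. With Cl- replicate 4 left out of the shared fit, 3 transcripts passed, among them ENSBTAT00000018261.6 (adjusted p = 0.0427, and 0.0427 to 0.462 over all alternatives).

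**Figure D2:**
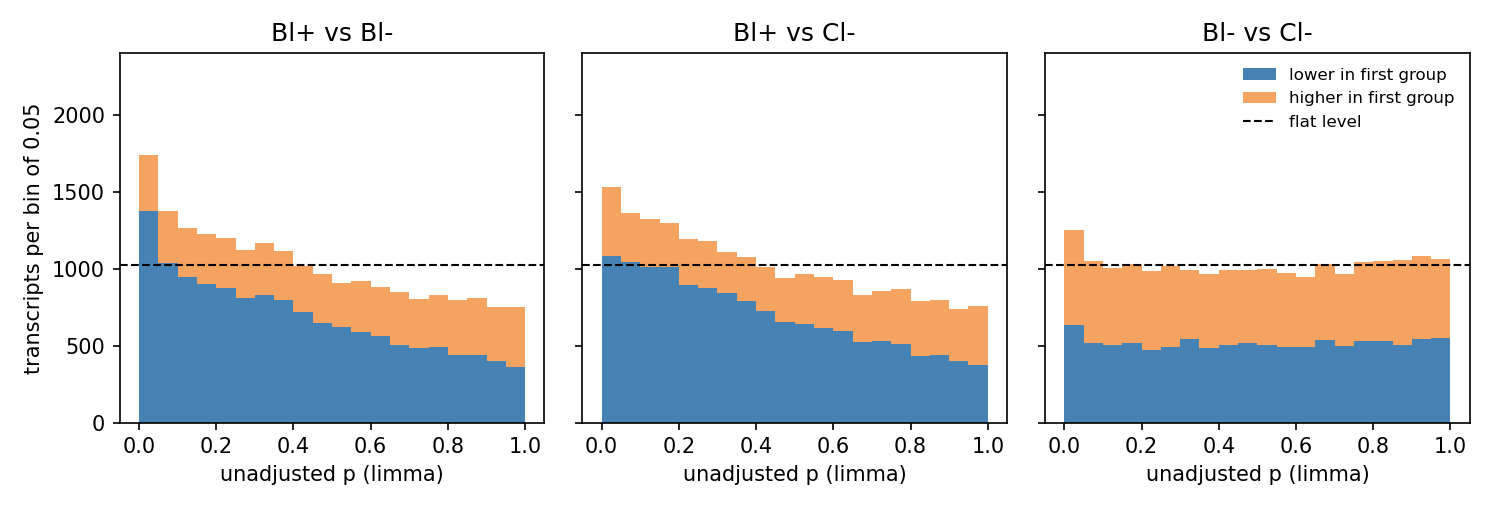
Number of transcripts (y axis) per bin of unadjusted limma p (x axis) in the 3 pairwise comparisons, split by whether the estimate was lower or higher in the group named first; the dashed line is the level of a flat distribution. The bin under 0.05 holds 1741 transcripts for Bl+ with Bl-, 1527 for Bl+ with Cl- and 1250 for Bl- with Cl-.

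Bl+ was compared with Cl- to set cumulus cells of oocytes with full development against those of oocytes that never divided. No transcript passed in limma here either. The smallest adjusted p, 0.120, belonged to ENSBTAT00000072423.1, at 1.43 to 2.46 TPM in Cl- and 0 to 0.741 TPM in Bl+. For 18051 transcripts (88.1%) the 95% interval lay inside a 2-fold change of TPM + 1. ENSBTAT00000018261.6 differed by -0.74 (SE 0.132, adjusted p = 0.292), with every Bl+ library at 58.0 to 89.2 TPM and every Cl- library at 93.4 to 130 TPM. The transcript of 812 bases was at 343 ± 34.7 TPM in Cl- (n = 4), and differed by 0.52 (SE 0.101, adjusted p = 0.332).

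At an unadjusted p under 0.05, 1527 transcripts differed between Bl+ and Cl-, of which 1079 were lower in Bl+ and 448 higher (70.7% lower). After rescaling by trimmed means 556 were lower and 756 higher (42.4% lower), after quantile normalization 567 and 857 (39.8%), and without Bl+ replicates 12 and 14 there were 516 and 340 (60.3%). Without Cl- replicate 1, 656 were lower. Before rescaling, all Bl+ libraries lay below all Cl- libraries for 353 transcripts and above them for 119, against 162.6 each by chance (0.794%). The lower level of Bl+ libraries (median difference -0.08) enters these counts. Limma without the variance trend, limma with array weights, and the fit without Bl+ replicate 10 each called 1 transcript.

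Bl- was compared with Cl- to separate cumulus cells by whether the oocyte cleaved, among oocytes that formed no blastocyst. One transcript, ENSBTAT00000072423.1 (2808 bases), fell by 1.48 on the log2 scale in Bl- (SE 0.185, adjusted p = 0.0246). It stood at 1.43 to 2.46 TPM in the 4 Cl- libraries, equal to 63.6 to 109 fragments, and at 7.82e-08 to 0.00198 TPM in the 5 Bl- libraries. In Bl+ it ranged from 0 to 0.741 TPM. No fold is given, since its level in Bl- was worth less than 1 fragment (0.0916 at most). With a pseudocount of 5 the difference was -0.45 (adjusted p = 0.0252). The call was lost with a pseudocount of 0.1 (-4.23, adjusted p = 0.544), in a fit of only these groups (0.0561) and without Bl+ replicates 12 and 14 (0.0775), with a range of 0.00214 to 0.544 over the alternatives.

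The call of ENSBTAT00000072423.1 between Bl- and Cl- was also lost when 1 library was left out, for 10 of the 14 libraries. Its adjusted p was 0.174, 0.173, 0.0725 and 0.0896 without Cl- replicates 1, 2, 3 and 4. It was 0.105 without Bl- replicates 5, 6 or 7, 0.104 without replicate 8, 0.109 without replicate 9 and 0.0612 without Bl+ replicate 13. The difference itself stayed between -1.55 and -1.38 with each library left out, and was -1.48 in the fit of only these groups. No transcript higher in Bl- passed. By the rule for identifiers, ENSBTAT00000063604.2 (2411 bases) was at 70.1 ± 5.67 TPM in Bl- (n = 5) and 55.3 ± 2.69 in Cl- (n = 4), and ENSBTAT00000026421.4 (903 bases) at 49.8 ± 2.09 and 40.9 ± 1.02. Their differences of 0.34 (SE 0.068) and 0.28 (SE 0.057) both had an adjusted p of 0.609. All Bl- libraries lay above all Cl- libraries for both, which were picked by smallest p. Bl+, whose oocytes also cleaved, was at 57.5 ± 3.78 and 41.7 ± 2.61 TPM (n = 5), near the Cl- means.

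**Figure D3:**
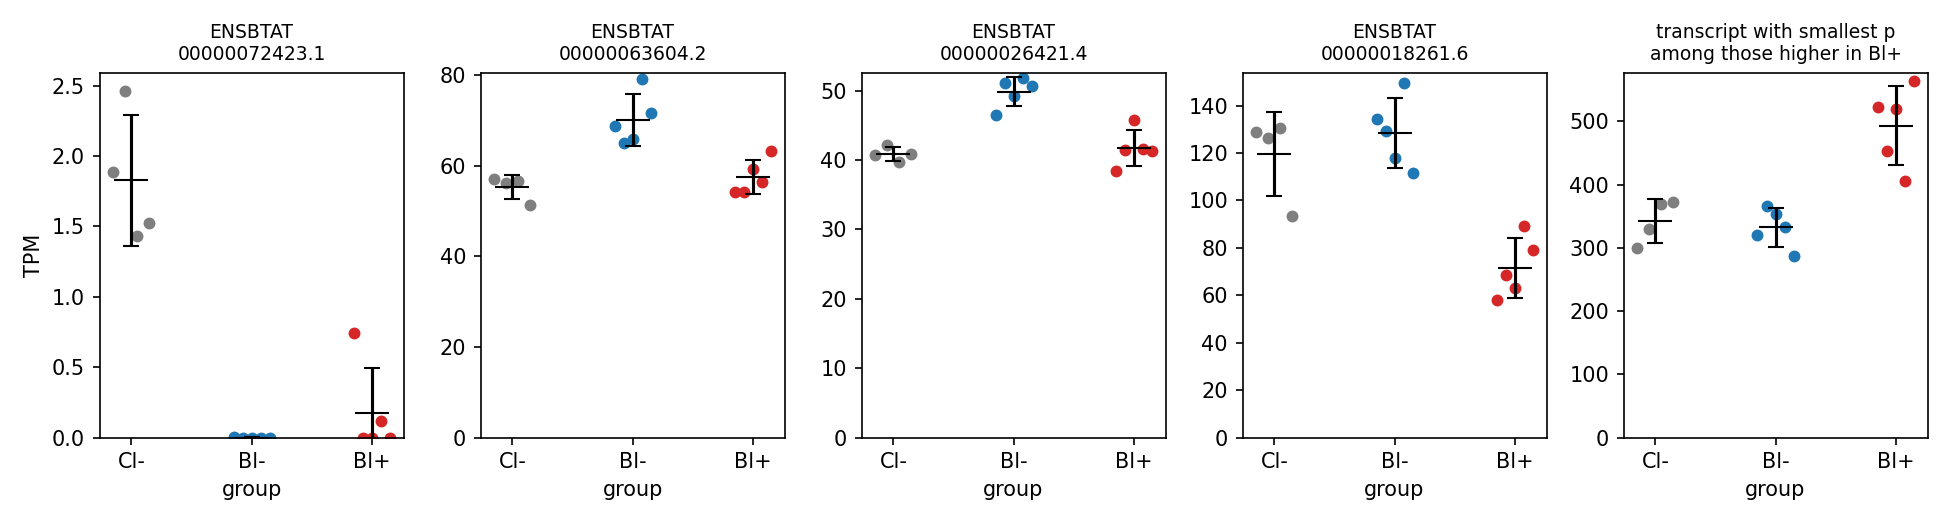
TPM (y axes, starting at 0) of 5 transcripts per library in the 3 groups (x axes), with 1 point per library and the mean ± SD as a bar. ENSBTAT00000072423.1 is at 1.43 to 2.46 TPM in Cl- and near 0 in Bl-, and ENSBTAT00000018261.6 is lower in the 5 Bl+ libraries than in the other 9.

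Between Bl- and Cl-, 1250 transcripts had an unadjusted p under 0.05, 634 lower and 616 higher in Bl- (50.7% lower). After rescaling by trimmed means 690 were lower and 468 higher (59.6% lower), and after quantile normalization 742 and 616 (54.6%). For 18459 transcripts (90.1%) the 95% interval lay inside a 2-fold change. All Bl- libraries lay below all Cl- libraries for 235 transcripts and above them for 255, against 162.6 each by chance.

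Bl+ was also set against the other 9 libraries, and Cl- against the other 10, to ask what was particular to each end of development. For Bl+ no transcript passed in limma, 4 had an adjusted p under 0.10, and 1764 had an unadjusted p under 0.05 (1357 lower and 407 higher, 76.9% lower). After rescaling by trimmed means 636 were lower and 904 higher (41.3% lower), after quantile normalization 594 and 956 (38.3%), with the 100 most abundant transcripts removed 1061 and 536 (66.4%), and without Bl+ replicates 12 and 14 there were 675 and 385 (63.7%). ENSBTAT00000018261.6 differed by -0.79 (SE 0.110, adjusted p = 0.0901) and the transcript of 812 bases by 0.54 (SE 0.084, adjusted p = 0.0928). Leaving out Cl- replicate 4 gave 1 call and leaving out Bl+ replicate 13 gave 2. Before rescaling, all 5 Bl+ libraries lay below the other 9 for 32 transcripts and above them for 13, against 10.2 each by chance (0.050%). Library level enters these counts too. For Cl- the sole call was ENSBTAT00000072423.1, higher by 1.39 (SE 0.163, adjusted p = 0.0122), and 1301 transcripts had an unadjusted p under 0.05, 464 lower and 837 higher (35.7% lower). After trimmed means 575 were lower and 599 higher (49.0%), and after quantile normalization 715 and 648 (52.5%). The number of calls was 0 without Cl- replicate 1, 2 or 4 and 2 without Bl- replicate 7. The joint test of the 3 groups called 1 transcript (adjusted p = 0.0492), and 1609 had an unadjusted p under 0.05. Of the fits with 1 library left out, only the one without Bl+ replicate 10 made a call.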

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

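The tests of a trend with transcript length on the lower share, of the 100 most abundant transcripts, of depth, of the log2 scale near 0 TPM and of shared reads were chosen after the results were seen. The other tests were written down before their results, but the form of the length correction that keeps each library's level was adopted, for both patterns it was used on, after a first form had been run.

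Among 45 comparisons of a library with the rest of its group, 5 found a library standing apart from the others by a Dixon test. For normally distributed values chance gives about 1 in 20 such cases, a rate that need not hold for values near 0 TPM. Cl- replicate 4 accounts for 3 of them. Its mean distance to the other Cl- libraries was 0.473, against 0.436 to 0.442 for the others. It held 51.3 TPM of ENSBTAT00000063604.2, against 56.2 to 57.0 in the other Cl- libraries, and 93.4 TPM of ENSBTAT00000018261.6, against 126.3 to 130.4. The other cases concern ENSBTAT00000072423.1, at 0.00198 TPM in Bl- replicate 5 with the other Bl- libraries lower, and at 0.741 TPM in Bl+ replicate 10 with the others at 0.116 or less.

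ENSBTAT00000072423.1 was the single transcript called between Bl- and Cl-. Of 100 splits of those 9 libraries, 5 gave a call (1 in the real split, 1 at most in another), so chance is not excluded. With a pseudocount of 0.1 the difference went from -1.48 (SE 0.185) to -4.23 (SE 0.691). Its adjusted p was 0.544 because the SE grew more than the difference. With a pseudocount of 5 the difference was -0.45 (adjusted p = 0.0252), so its size is set by the pseudocount. Over all alternatives the adjusted p ran from 0.00214 to 0.544. In 7 libraries the transcript was listed above 0 but below 0.5 of a fragment, as in 0.0439% of tested transcripts, which is consistent with reads shared with another transcript. Such sharing may therefore account for the values near 0. In limma the transcript was higher by 1.39 in Cl- than in the other 2 groups (SE 0.163, adjusted p = 0.0122). That call was also lost under some alternatives, so a difference tied to cleavage of the oocyte stays open.

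More transcripts were lower than higher in Bl+ against Bl- at an unadjusted p under 0.05. Removing each library's trend on length left 79.3% lower where its level was kept (72.0% at least with a library left out). The median difference was negative in all 5 classes of length, from -0.06 to -0.09. These values argue against a slope with length alone. A first form that also removed the level gave 45.7%, so the balance follows that level. Whether the level itself is tied to length was not tested. Rescaling by trimmed means gave 43.3% lower, but it centres every library, so a broad fall in Bl+ cannot be told apart from an effect of the fixed total. With the 100 transcripts of highest mean TPM removed and the rest rescaled, 67.4% were lower (59.96% at least with a library left out). The median difference went from -0.07 to -0.05. That fixed set took 28.6% ± 0.80 of the TPM in Bl+ and 27.1% ± 1.14 in Bl-, so its larger share may account for part and the rest is open. Without Bl+ replicates 12 and 14 the share was 63.2%, between the bounds set for those libraries as sole source and for neither, so their part is open. Of 100 splits of the 10 libraries, 22 had as many transcripts on the larger side (1374 in the real split, 4396 at most in another), and neither chance nor a difference tied to blastocyst formation is excluded. These splits were of values before rescaling, so they also sort libraries by level. The median log2(TPM + 1) of a library differed by -0.09 between Bl+ and Bl- (exact permutation test, p = 0.270).

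Bl+ libraries lay farther from each other than Bl- libraries did. Low depth of Bl+ replicates 12 and 14 is unlikely as a cause, since 4 other libraries were shallower than both. Removing the trend on length left 97.8% of the excess distance (0.0730 of 0.0746). Of 100 splits, 24 gave as large a difference (0.0746 in the real split, 0.127 at most in another), so chance is not excluded and a wider range among pools with full development stays open.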

How the results depend on the processing

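Results without Bl+ replicates 12 and 14, with the length trend removed, with the 100 most abundant transcripts removed and with robust variance estimation were chosen after seeing the data. Gene sums, gene lists and surrogate variables were planned and not run. No paired analysis was possible because the sources used here do not say which pools, if any, shared an animal or a day.

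The share of transcripts with an interval inside a 2-fold change of TPM + 1 ran from 76.2% to 98.5% for Bl+ with Bl-. It ran from 74.0% to 98.4% for Bl+ with Cl- and 77.4% to 98.5% for Bl- with Cl-. The lowest share came with a pseudocount of 0.1 and the highest with 5. All stayed within 1.5 times the main value, the bound used for a move, which so high a share could hardly pass. Calls between Bl+ and Bl- stayed at 0 in 27 of 28 alternatives. ENSBTAT00000063604.2 and ENSBTAT00000026421.4 kept their direction and stayed above the threshold in all 27. Where a value below moved, the cause was not tested unless stated.

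At an unadjusted p under 0.05, trimmed means gave 656 lower and 859 higher transcripts for Bl+ with Bl- and 556 and 756 for Bl+ with Cl-. Quantile normalization gave 683 and 910, and 567 and 857. With every transcript above 0 tested, which adds transcripts, 567 were higher for Bl+ with Bl- and 973 lower for Bl- with Cl-. With array weights 1096 were lower for Bl- with Cl-. Without Bl+ replicates 12 and 14, 567 were higher for Bl+ with Bl- and 516 lower for Bl+ with Cl-.

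Calls for Bl+ with Cl- rose from 0 to 1 with limma without trend and with array weights. Calls for Bl- with Cl- went from 1 to 0 with at least 5 TPM in 4 libraries, a filter ENSBTAT00000072423.1 cannot pass, with a pseudocount of 0.1 (-4.23, adjusted p = 0.544; -0.45 and 0.0252 with 5, which kept the call), with only the groups compared (adjusted p = 0.0561) and without Bl+ replicates 12 and 14 (adjusted p = 0.0775). Calls for Cl- with the other groups went to 0 with that filter, with a pseudocount of 0.1 and without both replicates, and to 3 with array weights. Calls for Bl+ with the other groups were 4 at an adjusted p under 0.10. The joint test went from 1 call to 0 with trimmed means, the stricter filter, a pseudocount of 0.1, no replicates 12 and 14, no length trend, the 100 most abundant transcripts removed and robust estimation.

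With each library left out in turn, calls ran from 0 to 3 for Bl+ with Bl- (3 without Cl- replicate 4), 0 to 1 for Bl+ with Cl-, for Bl- with Cl- and for the joint test, 0 to 2 for Bl+ with the others and 0 to 2 for Cl- with the others. Lower transcripts for Bl+ with Cl- ran from 656 to 1596. The difference of ENSBTAT00000072423.1 ran from -1.55 to -1.38.

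The mean distance between groups exceeded that within groups by 0.00216. With libraries left out this ran from -0.00398 to 0.0162, with -0.00351, -0.00225 and -0.00314 without Cl- replicates 1, 3 and 4, and -0.00314 and -0.00064 without Bl- replicates 5 and 9. It was -0.00237 with a pseudocount of 0.1. The one-sided permutation p lay between 0.101 and 0.575 in these alternatives, so the sign of this difference is not settled.

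Depth (28.6 to 39.8 M fragments, M being 1000000) limits values near 0. ENSBTAT00000072423.1 was at most 0.0916 of a fragment in Bl- and at 63.6 to 109 fragments in Cl-. The mean depth was 32.7 M in Bl- and 33.3 M in Cl-, so depth does not account for that difference. With 200 of 20488 transcripts changed, simulated 2-fold changes between Bl+ and Bl- were recovered for 57.4%, and for 87.8% of those above 10 TPM. With fewer transcripts changed the Benjamini-Hochberg cutoff is stricter, so these shares overstate recovery there.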

Other observations

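The relations with the first principal component and the contents of single splits were looked at after the results were seen. The counts over splits were planned.

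The order of the 14 libraries along the first principal component followed the number of transcripts at 1 TPM or more, which ran from 18259 in Bl+ replicate 14 to 19913 in Bl- replicate 5. Pearson's r was -0.985 (permutation p = 1e-05, the smallest 100000 resamples can give; adjusted 3e-05 over 3 relations) and Spearman's rho was -0.960 (p = 1e-05). Without the 2 libraries farthest from the median count r was -0.973. Both measures come from the same values, so the strength of the relation is partly built in. The share of TPM in the 100 most abundant transcripts of each library, ranked within it, went with the component at r = 0.734 (permutation p = 0.00304, adjusted 0.00456) and rho = 0.648 (p = 0.0149, adjusted 0.0223), and at r = 0.612 without the 2 farthest libraries. For fragments per library r was 0.270 (permutation p = 0.350) and rho 0.160 (p = 0.582), with r = 0.270 without the 2 farthest libraries.

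One other split of the 10 Bl+ and Bl- libraries gave far more than the real one. It set Bl- replicates 5, 6 and 7 with Bl+ replicates 10 and 11 against Bl- replicates 8 and 9 with Bl+ replicates 12, 13 and 14, and called 946 transcripts, with 4859 at an unadjusted p under 0.05. Its sides also differed in library level. The factors of the rescaling by trimmed means were 1.01 to 1.10 on the first side and 0.887 to 0.976 on the second. Whether so many calls reflect more than this level was not tested. The split was picked as the one with the most calls of 100. Every library on its second side scored higher on the first principal component than every library on its first, which is partly built in, since both come from the same values. A call appeared in 19 of 100 such splits, and 25 gave as many transcripts at an unadjusted p under 0.05 as the real one (1741 real, 4859 at most), so chance is not excluded for that count. As many transcripts separated in a direction in 11 (278 real, 1302 at most). The real count was 0, which all 100 splits reach, so the count of calls says nothing about chance there.

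The same holds for the 0 calls of Bl+ with Cl- (46 at most in another split) and of Bl+ with the other groups (2 at most), which all 100 splits reach. The counts that follow did not exclude chance. For Bl+ with Cl-, 22 of 100 splits gave as many transcripts at an unadjusted p under 0.05 (1527 real, 3512 at most) and 15 separated as many in a direction (353 real, 878 at most). For Bl- with Cl- it was 10 of 100 (1250 real, 1929 at most) and 24 for separation (255 real, 1006 at most). Over 100 splits of all 14 libraries, the joint test gave at least its 1 call in 11 (18 at most) and Cl- with the other groups its 1 call in 8 (3 at most). As many transcripts separated below the other 9 libraries in 6 splits (32 real, 131 at most, median of the others 5), and above them in 20 (13 real, 65 at most).

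The median difference between Bl+ and Bl- was -0.07 over all tested transcripts, but -0.00061 with trimmed means, 0.0023 with quantile normalization and -0.0091 without Bl+ replicates 12 and 14. Before such rescaling, with transcripts in 5 equal classes it was -0.10 in the class of lowest level and -0.04 in the highest, and -0.06 in the shortest class and -0.09 in the longest. Spread between libraries of a group, as the median SD of log2(TPM + 1), was 0.252 in Bl+, 0.209 in Bl- and 0.185 in Cl-. No transcript was at 1 TPM or more in all libraries of one group and listed at exactly 0 in all of another, a criterion that leaves out ENSBTAT00000072423.1, at 1.43 TPM or more in Cl- and at most 0.0916 of a fragment in Bl-.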
